A study of Mus musculus with 24 samples.

How the data were processed

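The samples were poly(A) RNA libraries of the duodenum, ileum and colon of C57BL6J wild-type mice, made with a NEBNext Ultra II kit per the labels' protocols. The labels give 4 treated and 4 vitamin D-deficient samples per tissue, 2 females of 4 among the treated and 1 of 4 among the deficient, with ages of 10 to 14 whose unit is not stated. Reads were mapped to the mouse genome with CLC Genomics Workbench, per the labels' protocols, whose text stops short, while the submitters' processing notes name kallisto 0.45.0, DESeq 1.14.0, DESeq2 and the mm9 build without saying what each was used for. The deposited values are FPKM per gene symbol, one column per library, for 21441 genes per table. Gene positions were taken from the gencode vM1 annotation on NCBIM37, the assembly of mm9, and reads of overlapping or near-identical genes may be divided between them in a way the labels do not state.

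Each tissue has one table with 8 libraries and one with 7, without deficient minusD5718. The 8-library ileum table equals the 8-library duodenum table in 171528 of 171528 values, so the ileum was analysed from its 7-library table with 4 treated and 3 deficient libraries. This departs from the plan of 4 against 4. In the duodenum and colon the 7- and 8-library values differ by one constant per library, and the 8-library tables were used. In each tissue 3 columns of the deficient group are named Vehicle. They were taken as that group because the tables are named for MinusD against 3xD and hold no other group. The labels give no treatment for deficient samples, though their protocol text on injections is the same for all samples, so whether vehicle was injected is not given in the sources used here. The columns carry serial or 4-digit numbers that the labels do not tie to their replicates, so the labels' sex and age could not be assigned to libraries, and the presence of Xist reads served in their place as an alternative. The pooled counts of Xist and Ddx3y were set against the labels' numbers of females per group.

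The FPKM values move in steps of whole reads. The reads behind them were recovered for 84.1%, 83.9% and 83.8% of genes expressed in several libraries of the duodenum, ileum and colon. They had to lie within 0.0001 of a whole number, and gave the depth per library. This depth leaves out the other genes. A gene listed at 0 in some libraries and well expressed in others, such as Oaz1, may have had its reads assigned elsewhere, so such genes are given as listed values.

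Within each tissue, genes with at least 1 FPKM in at least 3 libraries were tested on log2(FPKM + 1) with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, treated against deficient, with no covariate and Benjamini-Hochberg adjustment at 0.05. Tests were two-sided. Differences in response between tissues were tested as interaction contrasts in one fit of 6 group means over the 23 libraries. Exact permutation tests of single genes used every split of the libraries. Gene lists fixed before the data were examined, 45 in all, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, for lists with at least 3 members past the filter: 44 in the duodenum and 43 in the ileum and in the colon, adjusted over the lists of a tissue. The labels' quantitative PCR panel is one of these lists. Overlaps were set against those of independent lists (Fisher's exact test) and against those of other splits of the 8 library numbers, applied to both tissues at once and without deficient minusD5718 in the ileum.

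Tests chosen after the data were seen, voom and the overlaps at an unadjusted p among them, are named below. The limma and camera tests, fry beside camera, the filter, the lists and the rule for named genes were chosen before the data were examined. The rule took the panel genes and Vdr, genes past the threshold with groups fully apart, the 3 smallest p in a direction with few calls, the 3 members with the smallest p of each list that passed, the 5 genes with the smallest interaction p per pair of tissues, and members past the threshold of the lists of calcium transport, the vitamin D receptor and its metabolism, and zinc and manganese transport. Those that passed over all genes were Cyp24a1, Ap1g1 and BC023829 in the duodenum. The naming scheme of the libraries was noticed in the columns and is given within schemes and as a covariate. Other alternatives covered the pseudocount (0.1, 0.5), the filter (none, mean FPKM of at least 1, 5 FPKM), quantile and median-ratio rescaling, the authors' 7-library tables, each library left out in turn, array weights, robust eBayes, a shared fit of all tissues and voom on recovered reads.

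For paired designs, deviations from group means were correlated between libraries of the same number in different tissues. All 7 pairs of the duodenum and ileum lay over 0.1 (lowest 0.11, median 0.28), against 7 of 8 for the duodenum and colon (lowest -0.07) and 6 of 7 for the ileum and colon (lowest 0.03). Only the duodenum and ileum thus had every pair over 0.1. The number also linked libraries of the colon, with medians of 0.22 with the duodenum and 0.28 with the ileum. Libraries of the same group with other numbers had medians of -0.08 and -0.12 there, and of -0.08 for the duodenum and ileum. As deviations cancel out within a group, these negative medians follow from the positive ones and give no separate baseline. Pairing by number is thus not excluded for the colon. The main fit between tissues treats libraries as independent. Values with the number as a block, run for every pair of tissues, stand beside results that they change.

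Tests were checked on simulated counts drawn from the real means, with genes changed by known folds. At 8-fold, 98.5%, 97.0% and 97.0% of changed genes were found in the duodenum (9395 genes), ileum (9705) and colon (10234), and 5.09%, 5.32% and 4.67% of unchanged genes had p under 0.05. Simulated genes varied independently, without differences between libraries by naming scheme. Many were changed at once, which loosens the adjusted threshold. These shares may thus overstate what the test finds in the real data. Recovery of reads and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Depth limits low values: a library of 14460284 to 44522055 recovered reads resolves small FPKM in steps of single reads, and counts of reads cover counting error only. Differences of genes near 0 in one group depend on the pseudocount: with 0.1, 33 of 166 values of single genes and lists were over 1.5 times larger and 1 smaller, and by voom 35 of 96 and 3.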

Results

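Poly(A) RNA was sequenced from the duodenum, ileum and colon of wild-type C57BL6J mice, to find genes that respond to vitamin D along the intestine. In each tissue, mice given calcitriol (1,25-dihydroxyvitamin D3, the hormone form of vitamin D) were set against vitamin D-deficient mice, whose labels give no treatment. Treated mice received 3 injections of 1 ng per g body weight, at 48, 24 and 6 h before the end. The values used here cover 23 libraries: 4 treated and 4 deficient in the duodenum, 4 and 3 in the ileum, and 4 and 4 in the colon. Whole reads recovered from the deposited values came to 22324535 to 44522055 per library in the duodenum, 19509117 to 43244319 in the ileum and 14460284 to 29534808 in the colon.

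Libraries are named by group and by their column. One naming scheme uses serial numbers (treated 1, deficient 1, 2 and 3). The other uses 4-digit numbers, with the region's letter left off here (treated 3xD5711, 3xD5720 and 3xD5734, deficient minusD5718, which the ileum lacks). In the figures these carry the number alone. The columns of deficient 1, 2 and 3 are named Vehicle, and were taken as the deficient group because the tables compare MinusD with 3xD. The schemes nearly coincide with treatment, so differences within each scheme (1 treated library against 3 deficient ones, and 3 against 1) stand beside the pooled ones. In the ileum only the serial scheme holds both groups, so a fit with the scheme compares treated 1 alone with the deficient libraries. Recovered reads followed the scheme in the colon, at 14460284 to 22974440 in 4-digit and 26772575 to 29534808 in serial libraries. In the duodenum and ileum the ranges of the schemes overlapped. Depth thus nearly coincides with treatment in the colon. The counts of libraries with more Xist than Ddx3y matched the number of females in the labels in 5 of the 6 groups. None of the 3 deficient ileal libraries had more Xist than Ddx3y, where the labels give 1 female of 4. Deficient minusD5718, which the ileum lacks, had more Xist than Ddx3y in the duodenum (36.52 against 0.07 FPKM) and in the colon (88.54 against 0.13). The naming schemes nearly coincide with sex as well: more Xist than Ddx3y was found in 0 of 4 serial and 3 of 4 4-digit libraries of the duodenum and of the colon, and in 0 of 4 and 2 of 3 of the ileum.

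In the duodenum, calcitriol raised Cyp24a1, which encodes the enzyme that inactivates the hormone, from 0.114 ± 0.203 to 346.5 ± 236.2 FPKM (mean ± SD, n = 4 in each group). S100g, which encodes the calcium-binding protein calbindin-D9k, stood at 9133 ± 4023 FPKM in treated mice against 2144 ± 1612, with treated 3xD5720 (3146) below deficient minusD5718 (3873), and the apical calcium channel gene Trpv6 at 22.7 ± 26.8 against 1.56 ± 2.34. The manganese exporter gene Slc30a10 stood at 98.3 ± 11.01 FPKM against 46.1 ± 21.8, and the sugar-phosphate transporter gene Slc37a2 at 92.4 ± 45.9 against 30.2 ± 17.7. Vdr, the gene of the vitamin D receptor, stood at 91.9 ± 13.2 FPKM in treated mice and 117.5 ± 37.9 in deficient ones, a log2 difference of -0.30 ± 0.25 (SE; adjusted p = 0.665; -0.54 to -0.15 when single libraries were left out). Trpv5, a relative of Trpv6, lay under the expression filter in all 3 tissues.

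Limma called 3 of 11734 duodenal genes, 1 higher and 2 lower, all tests being two-sided. Cyp24a1 (chromosome 2, 170308208 to 170322645, NCBIM37) rose by 7.91 ± 0.59 in log2 (SE, n = 4 and 4, adjusted p = 0.0034), with all 4 treated libraries above all deficient ones. Its difference was 8.28 within the serial and 7.46 within the 4-digit libraries, and 7.87 ± 0.72 (adjusted p = 0.0452) with the naming scheme in the fit. By voom on the recovered reads, which adds less to values near 0, it was 12.65 (adjusted p = 0.0025). Of the panel of 6 genes that the labels list for quantitative PCR, 5 were tested and 5 were higher at a p adjusted over the list alone. That count is not independent evidence, since the list may have been chosen on these samples. S100g was higher by 2.41 ± 0.75 (3.35 serial, 0.90 4-digit; p adjusted over the list alone 0.0163, adjusted p over all genes 0.499). For Trpv6 the values were 3.00 ± 0.76 (2.18 and 1.84; 0.00838 and 0.483), for Slc30a10 1.26 ± 0.41 (1.67 and 0.57; 0.0163 and 0.499) and for Slc37a2 1.76 ± 0.66 (2.69 and 0.70; 0.0257 and 0.499). The panel count was 4 without treated 1 or without treated 3xD5734, and 2 with the naming scheme in the fit (Cyp24a1, 1.92e-05, and Trpv6, 0.0265). Slc30a10 ran from 0.78 to 1.47, Slc37a2 from 1.09 to 2.14 and S100g from 1.71 to 2.86 when single libraries were left out.

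The 2 genes that fell in the duodenum are Ap1g1, which encodes a subunit of the clathrin adaptor AP-1, and BC023829. Ap1g1 was listed at 0 to 0.0598 FPKM in treated and at 1.05 to 1.74 FPKM in deficient libraries (log2 -1.15 ± 0.13, adjusted p = 0.0392; -1.18 serial, -1.02 4-digit). BC023829 was listed at 0 to 0.0816 against 0.944 to 1.37 FPKM (log2 -1.06 ± 0.12, adjusted p = 0.0392; -1.10 and -1.02). Neither passed when any one library was left out: the adjusted p was 0.0678 to 0.181 for Ap1g1 over the 8 libraries, and for BC023829 it was 0.0875 without treated 1, 0.108 without treated 3xD5711, 0.156 without treated 3xD5720, 0.127 without treated 3xD5734 and 0.0517 without deficient 3. The log2 differences then ran from -1.20 to -1.06 for Ap1g1 and from -1.11 to -1.05 for BC023829, so the calls ended while the differences hardly moved. These log2 differences depend on the pseudocount of 1, as one group lies near 0: with 0.1 they were -3.50 (adjusted p = 0.112) and -3.40 (0.158), and by voom on the recovered reads -6.69 (0.0146) and -6.05 (0.0129). BC023829 fell under the filter without deficient minusD5718, 1 or 2. With the naming scheme in the fit the adjusted p was 0.273 for both. The gene count was 1 without treated 3xD5711, 3xD5720 or 3xD5734 or without deficient 2. Among genes that did not pass, those with the smallest p were Krt7, a keratin of simple epithelia (58.6 ± 10.9 FPKM against 27.4 ± 3.93; log2 1.07 ± 0.15, adjusted p = 0.154; 0.88 serial, 0.94 4-digit) and Zfp131 (1.13 ± 0.18, 0.23; 1.15 and 1.42). Snord17, a small nucleolar RNA gene, was listed at 0 in all treated libraries (adjusted p = 0.0822), with 7 reads over the deficient ones. Without deficient 3 Zfp131 passed (0.0267), and without deficient 1 Snord17 passed (0.0151). At an unadjusted p under 0.05 there were 473 genes higher and 630 lower, where 587 of either sign come by chance; other splits of these 8 libraries gave a median of 372 and up to 2855. The groups were fully apart for 4.37% of genes, where chance gives 2.86%. On simulated data of these duodenal libraries the test found 33.8% of genes changed 2-fold and 92.5% of those changed 4-fold, over 9395 genes. Simulated genes varied independently, so these shares may be too high.

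**Figure D1:**
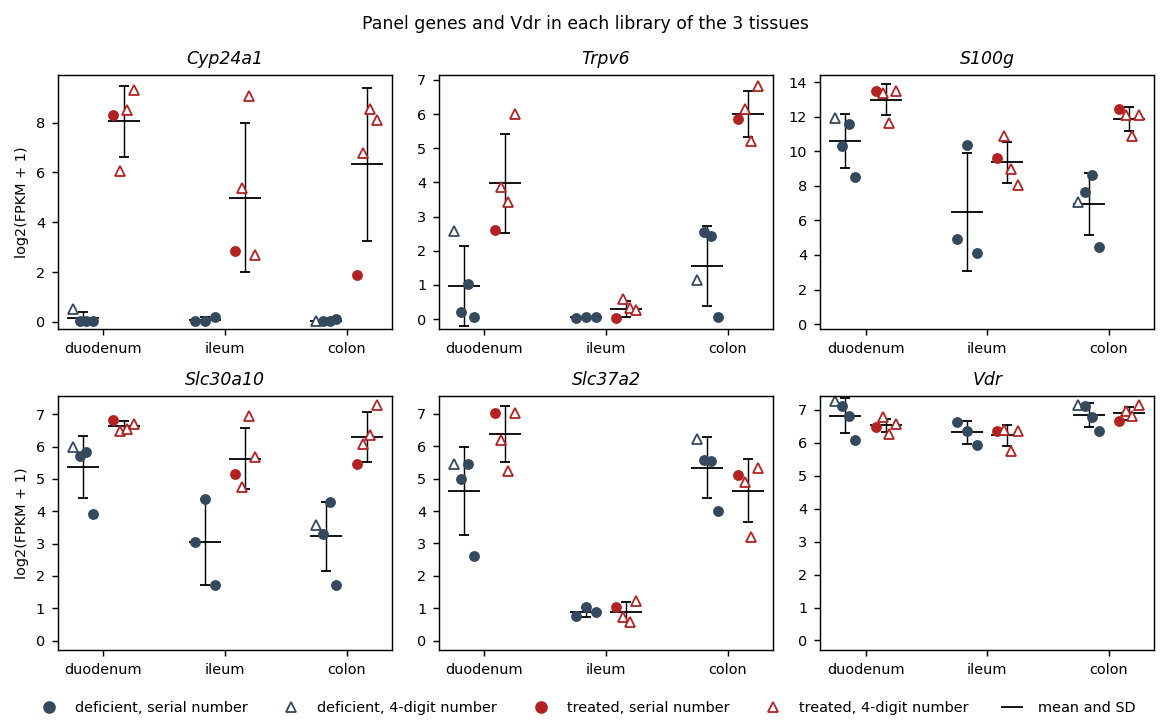
Expression of 5 panel genes and Vdr as log2(FPKM + 1) in each library of the 3 tissues, with deficient and treated libraries side by side, filled circles for serial and open triangles for 4-digit numbers, and bars for the mean and SD. Treated Cyp24a1 lies at 64.9 to 640.5 FPKM in the duodenum, and at 2.67 FPKM in the lowest treated colonic library.

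T and NK cell markers were lower as a list in the treated duodenum by camera at a preset correlation, and 0 members passed over all genes. Of 17 tested T and NK cell markers, 0 had a positive log2 difference (mean -0.58, adjusted p = 2e-07 in camera, limma's test of a list against other genes, and adjusted p = 0.699 with an estimated correlation). The mean was -0.13 within the serial and -0.54 within the 4-digit libraries. Zap70, a T cell receptor kinase gene, stood at 0.864 ± 0.819 FPKM in treated and 2.64 ± 0.632 in deficient mice, and Il2rb, a cytokine receptor gene, at 2.75 ± 1.02 against 5.08 ± 1.15. The 13 B and plasma cell markers also fell as a list (-0.68, adjusted p = 0.00042; 0.18 serial, -0.68 4-digit), and with an estimated correlation their adjusted p = 0.699. Ms4a1, which encodes the B cell protein CD20, stood at 1.64 ± 1.72 against 3.88 ± 0.954 FPKM. Interferon response genes fell as a list (-0.18, adjusted p = 0.0206; -0.28 and -0.23, and adjusted p = 0.699 with an estimated correlation), though 10 of 29 had a positive difference, and 2 were lower at a p adjusted over the list alone. Genes of MHC class II, which presents antigen to T cells, fell as a list (-0.47, adjusted p = 0.0246; -0.12 and -0.34), as did cholesterol synthesis genes (-0.17, 0.0246; -0.23 and 0.28). For both the adjusted p = 0.806 with an estimated correlation.

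Calcium transport genes rose as a list in the duodenum (11 tested, mean log2 0.69, adjusted p = 0.0406; 0.75 serial, 0.35 4-digit, and adjusted p = 0.699 with an estimated correlation). Of its members 3 were higher at a p adjusted over the list alone. The panel genes Trpv6 and S100g are members of this list too, and its median log2 was 0.12. Cldn2, which encodes a claudin that lets cations pass between cells, stood at 94.9 ± 70.8 FPKM against 28.1 ± 7.66 (log2 1.51 ± 0.42, adjusted p over all genes = 0.499; 0.79 and 1.30). The panel list as a whole rose too (mean 3.27, adjusted p = 6.86e-07; 3.63 and 2.29, and adjusted p = 0.699 with an estimated correlation). Enteroendocrine markers (0.17, adjusted p = 0.0246; 0.13 and 0.07, and adjusted p = 0.699 with an estimated correlation) and ileum markers (0.70, 0.0406; 0.45 and 0.38, and adjusted p = 0.699 with an estimated correlation) passed with them. So did PPAR-alpha and fasting genes (0.47, 0.0394; 0.02 and 0.05, and adjusted p = 0.806 with an estimated correlation) and stomach markers (2.89, 0.0246; 0.12 and -0.61, and adjusted p = 0.806 with an estimated correlation). Sst, which encodes somatostatin, stood at 171 ± 17.7 FPKM against 136 ± 18.9, and Acaa2, an enzyme gene of fatty acid oxidation, at 274 ± 47.3 against 204 ± 45.0. Fabp6, the ileal bile acid-binding protein, reached 280.9 FPKM in treated 3xD5711 and 0.926 to 89.4 FPKM in the other 7 libraries. Among lists that did not pass were those of the vitamin D receptor and its metabolism (adjusted p = 0.479), phosphate transport (0.853), tight junctions (0.256), zinc and manganese transport (0.123) and proliferation (0.149).

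Camera called 11 of 44 lists in the duodenum, 0 of them with an estimated correlation and 0 by fry. Fry's test for changes in either direction called 2, the panel (adjusted p = 0.0193) and the list of the vitamin D receptor and its metabolism (0.000382). Cyp24a1 belongs to both and is the 1 member of the receptor list that passed over all genes. The median log2 of that list was 0.01. Of all tested lists, 14 of 44 lists had the opposite sign within the serial and 13 of 43 within the 4-digit libraries, as did 4 and 3 of 43 named genes. The T and NK cell and panel lists passed whichever library was left out. Without deficient 3 the count was 4, and the adjusted p was 0.156 for B and plasma cells, 0.0609 for interferon, 0.418 for MHC class II, 0.388 for cholesterol, 0.17 for calcium, 0.216 for enteroendocrine, 0.228 for ileum, 0.46 for PPAR-alpha and 0.222 for stomach lists. Without treated 3xD5711 the count was 7, with 0.083 for calcium, 0.0855 for PPAR-alpha, 0.166 for enteroendocrine, 0.166 for ileum and 0.163 for stomach lists. Without treated 3xD5720 the p was 0.0942 for cholesterol, 0.135 for MHC class II, 0.33 for PPAR-alpha and 0.0514 for stomach lists, and without deficient 2 it was 0.0889 for cholesterol, 0.0889 for PPAR-alpha and 0.053 for stomach lists. The calcium list also missed without treated 1 (0.0788), treated 3xD5734 (0.0784) or deficient 1 (0.0539), the interferon list without treated 1 (0.161) and the ileum list without treated 3xD5734 (0.0512). Relative to all genes, the means of lists that moved most ran from 0.181 to 0.677 for PPAR-alpha (0.461 with all libraries), -0.631 to -0.183 for MHC class II (-0.476), -0.347 to -0.082 for cholesterol (-0.178), 0.414 to 0.925 for ileum (0.699) and 2.250 to 4.539 for stomach lists (2.885). With the naming scheme in the fit 3 of the 11 lists still passed, the panel (mean 2.96), T and NK cells (-0.33) and interferon response (-0.25). The adjusted p was then 0.0712 for calcium, 0.144 for B and plasma cells, 0.322 for MHC class II, 0.178 for enteroendocrine, 0.276 for ileum, 0.153 for stomach and 0.945 for cholesterol and for PPAR-alpha lists. Another 3 passed in that fit alone: proliferation (0.17), enteric neuron and glia (0.52) and smooth muscle markers (0.27).

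The duodenal libraries differed in stomach transcripts by naming scheme. Gkn1, a gastric mucosal gene (chromosome 6, 87295647 to 87300917, NCBIM37), was listed at 321.5 to 560.0 FPKM in the 4 libraries with 4-digit numbers and at 0 to 0.0282 in the 4 serial ones. Tff2, a trefoil peptide gene of the gastric glands, ran from 3516 to 6685 FPKM against 33.3 to 202. All 7 tested stomach markers parted the libraries in this way, and 0 parted treated from deficient libraries.

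**Figure D2:**
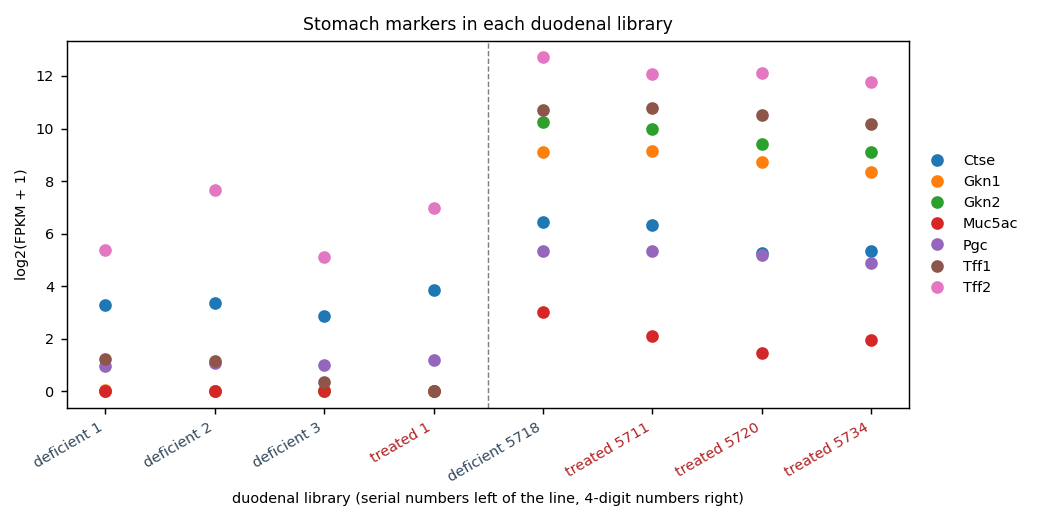
Stomach markers as log2(FPKM + 1) in each duodenal library, serial numbers left of the dashed line and 4-digit numbers right of it, with treated libraries named in red. Deficient minusD5718 (Gkn1 at 557 FPKM) lies with the treated libraries of its scheme, and treated 1 (0 FPKM) with the serial deficient ones.

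In the ileum, Cyp24a1 was higher in each treated library, at 6.12, 40.3, 543 and 5.34 FPKM, than in any deficient one, at 0.0265, 0.0157 and 0.153. Slc30a10 stood at 58.0 ± 43.4 FPKM (n = 4) against 9.83 ± 9.05 (n = 3). S100g stood at 848 ± 711 against 462 ± 760 FPKM, Slc37a2 at 0.885 ± 0.386 against 0.862 ± 0.191 and Vdr at 74.8 ± 14.3 against 80.1 ± 19.4. Trpv6 lay under the expression filter, at 0.238 ± 0.204 against 0.0333 ± 0.0173 FPKM. Among genes with the smallest p, Ap1g1 was listed at 0.913 to 2.06 FPKM in treated and at 0 to 0.00507 in deficient libraries, the opposite of its order in the duodenum. Oaz1, the ornithine decarboxylase antizyme gene, was listed at 0 to 0.985 FPKM in treated and at 2.18 to 7.61 in deficient libraries.

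Limma called 0 of 12149 ileal genes, where 709 had an unadjusted p under 0.05 (607 by chance, and a median of 377.5 and up to 2070 over other splits of the 7 libraries), voom on the recovered reads called 1, and the smallest adjusted p was 0.706. Cyp24a1 differed by 4.90 ± 1.40 (adjusted p = 0.706; 2.74 within the serial libraries) and Slc30a10 by 2.57 ± 0.68 (0.706; 2.10). These 2 of 4 tested panel genes were higher at a p adjusted over the list alone (0.0155 each), which is not independent evidence as the list may have been chosen on these samples. For S100g (2.87 ± 1.41; 3.10 serial) that p was 0.0995, and for Slc37a2 (0.00 ± 0.19; 0.16) it was 0.999; the panel count was 3 without deficient 2 and 0 with the naming scheme in the fit. S100g ran from 1.70 to 4.83 when single libraries were left out. Vdr differed by -0.09 ± 0.22 (adjusted p = 0.896; 0.04 serial). The log2 differences of Ap1g1 and Ndufb11 were 1.33 ± 0.19 and 0.91 ± 0.17 (1.27 and 0.51 serial), and those of Oaz1, Hist2h2aa2 and Wdr89 -2.27 ± 0.38, -1.83 ± 0.35 and -1.27 ± 0.26 (-2.52, -1.16 and -0.54), each with an adjusted p of 0.706. By voom Ap1g1 differed by 8.41 (adjusted p = 0.000276), Cyp24a1 by 8.96 (0.0881) and Oaz1 by -6.34 (0.085). The groups were fully apart for 6.56% of genes, where chance gives 5.71%. With 4 against 3 libraries the exact permutation p, taken as 2 times the smaller one-sided p, cannot go below 0.0571. On simulated data over 9705 genes limma found 9.0% of genes changed 2-fold and 86.6% of those changed 4-fold. As simulated genes varied independently, these shares may be too high.

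PPAR-alpha and fasting genes rose as a list in the ileum (15 of 16 positive, mean log2 0.65, adjusted p = 3.13e-05; 0.17 serial, and adjusted p = 0.861 with an estimated correlation). Fabp1, a fatty acid-binding protein gene, stood at 923 ± 859 FPKM (n = 4) against 211 ± 34.0 (n = 3), and Pdk4, a kinase gene that limits glucose oxidation, at 14.8 ± 17.1 against 2.33 ± 1.23, of which treated 3xD5720 had 40.18 and the other treated libraries 3.159 to 9.336 FPKM (log2 1.77, 1.12 to 2.23 when single libraries were left out, 0.39 serial). The log2 difference of Fabp1 was 1.73, and 1.17 to 2.04 when single libraries were left out. The panel list rose (2.59, adjusted p = 0.0194; 2.03 serial, and adjusted p = 0.861 with an estimated correlation). Exocrine pancreas markers fell (-1.29, adjusted p = 3.13e-05; -1.29 serial, and adjusted p = 0.861 with an estimated correlation): the protease gene Cela2a was listed at up to 106.7 FPKM in deficient libraries and up to 6.39 in treated ones. T and NK cell markers (-0.47, adjusted p = 0.00491; 0.20 serial, and adjusted p = 0.888 with an estimated correlation) and Paneth cell markers (-0.19, 0.0338; -0.26, and adjusted p = 0.888 with an estimated correlation) fell too. Defa22, an antimicrobial defensin gene of Paneth cells whose reads near-identical relatives can share, stood at 14040 ± 2981 FPKM against 22960 ± 8829. When single libraries were left out, the log2 difference ran from -3.11 to -0.87 for Cela2a (-2.18 with all) and from -0.86 to -0.37 for Defa22 (-0.67). Sex-linked genes fell (-1.72, adjusted p = 0.0398; -0.07 serial, and adjusted p = 0.861 with an estimated correlation), where 2 of 4 treated and 0 of 3 deficient libraries had more Xist than Ddx3y.

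Camera called 6 of 43 lists in the ileum, 0 with an estimated correlation and 0 by fry. With the naming scheme in the fit, the ileal differences are those within the serial libraries, treated 1 against deficient 1, 2 and 3. The means were then 0.17 for PPAR-alpha, 2.03 for the panel, -1.29 for pancreas, -0.26 for Paneth, 0.20 for T and NK cell and -0.07 for sex-linked lists. They rest on 1 treated library and do not tell whether a list holds beside the scheme. Of all tested lists, 18 of 39 lists and 4 of 32 named genes had the opposite sign within the serial libraries. The count was 10 without treated 3xD5720, 13 without deficient 2 and 2 without deficient 3. PPAR-alpha genes passed whichever library was left out. The pancreas list missed without deficient 1 (mean relative to all genes -0.36, adjusted p = 0.118), and the panel without deficient 1 (0.0704) or deficient 3 (0.271). The T and NK cell list missed without treated 3xD5734 (0.0907) or deficient 3 (0.486), and the Paneth list without treated 1 (0.124), treated 3xD5734 (0.0907) or deficient 3 (0.607). The sex-linked list missed without treated 3xD5711 (0.12), treated 3xD5720 (0.0868), deficient 1 (0.114) or deficient 3 (0.252). Relative to all genes, the mean ran from 0.426 to 0.803 for PPAR-alpha (0.641 with all libraries), 2.122 to 4.3 for the panel (2.575), -1.954 to -0.357 for pancreas (-1.298), -0.716 to -0.205 for T and NK cells (-0.479), -0.353 to 0.006 for Paneth (-0.204) and -2.391 to -1.068 for sex-linked lists (-1.728).

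In the colon, 4 of 5 tested panel genes had every treated library above every deficient one. Trpv6 was at 68.4 ± 31.7 FPKM in treated and 2.62 ± 2.35 in deficient mice (n = 4 each), S100g at 4034 ± 1531 against 186 ± 157, Cyp24a1 at 189 ± 165 against 0.0303 ± 0.0343 and Slc30a10 at 86.7 ± 48.8 against 10.1 ± 6.65. Atp2b1, which encodes the plasma membrane pump that extrudes calcium, stood at 114.4 ± 10.7 against 55.4 ± 8.66 FPKM. Slc37a2 stood at 27.4 ± 13.5 against 45.5 ± 24.3 FPKM and Vdr at 119.4 ± 16.5 against 117.0 ± 28.2. Fermt3, an integrin activator gene of blood cells, was listed at 0.244, 0, 0 and 0 FPKM in treated libraries and at 1.46 to 3.63 in deficient ones.

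Limma called 0 of 12746 colonic genes, where 746 had an unadjusted p under 0.05 (637 by chance, and a median of 482.5 and up to 2112 over other splits of the 8 libraries), voom on the recovered reads called 0, and the smallest adjusted p was 0.109. Trpv6 (chromosome 6, 41570620 to 41586404, NCBIM37) differed by 4.46 ± 0.56 (4.18 serial, 4.90 4-digit; adjusted p = 0.109, 0.000117 adjusted over the list alone), S100g by 4.93 ± 0.78 (5.52 and 4.64; 0.275 and 0.000365), Slc30a10 by 3.08 ± 0.55 (2.35 and 3.00; 0.345 and 0.000552) and Cyp24a1 by 6.28 ± 1.26 (1.83 and 7.78; 0.456 and 0.000939). Each had all 4 treated libraries above all deficient ones, for which the exact permutation p is 0.0286, the smallest that 4 against 4 can give. With Slc37a2 at -0.71 ± 0.56 (0.08 and -1.77; 0.9 and 0.238), 4 of 5 tested panel genes were higher at a p adjusted over the list alone, which is not independent evidence since the list may have been chosen on these samples. The panel count was 5 without deficient 3, and Slc37a2 ran from -1.16 to -0.23 leaving out single libraries. Cyp24a1 was at 2.67 FPKM in treated 1; without that library its log2 difference was 7.76 (adjusted p = 0.0005) and the gene count 1. Without deficient 3 the gene count was 3, Fermt3 among them (adjusted p = 0.0431). Atp2b1 differed by 1.04 ± 0.13 (adjusted p = 0.109; 0.99 and 0.79), Rac3 by 0.78 ± 0.12 (0.275; 1.00 and 0.62) and Fermt3 by -1.72 ± 0.21 (0.109; -1.41 and -2.00). By voom Cyp24a1 differed by 11.33 (adjusted p = 0.769) and Fermt3 by -6.38 (0.441). Slc16a3, a lactate exporter gene, differed by -0.82 ± 0.14 (0.275; -0.59 and -0.81), Stx2, a syntaxin gene, by -1.09 ± 0.20 (0.345; -1.30 and -0.98) and Vdr by 0.05 ± 0.19 (0.976; -0.08 and -0.18). The groups were fully apart for 4.54% of genes, where chance gives 2.86%, and on simulated data over 10234 genes the test found 23.9% of genes changed 2-fold and 79.1% of those changed 4-fold. In the real colon Slc30a10, Trpv6, S100g and Cyp24a1 differed by more than 8-fold without passing over all genes. The simulated shares do not carry over to these genes.

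Calcium transport genes rose as a list in the colon (11 tested, mean log2 1.01, adjusted p = 0.000262; 1.01 serial, 0.97 4-digit, and adjusted p = 0.191 with an estimated correlation), and 4 members were higher at a p adjusted over the list alone. The calcium members Trpv6 (log2 4.46) and S100g (4.93) are panel genes too, so this list is not independent of the panel. The panel list rose as well (3.61, adjusted p = 1.95e-07; 2.79 and 3.71, and adjusted p = 0.221 with an estimated correlation). Adipocyte markers rose (7 of 8 positive, 0.56, adjusted p = 0.000324; 0.65 and 0.69, and adjusted p = 0.732 with an estimated correlation): Fabp4, a fatty acid-binding protein gene of fat cells, stood at 274 ± 45.9 against 166.5 ± 49.9 FPKM. PPAR-alpha genes (0.45, 0.000221; -0.06 and 0.24), xenobiotic metabolism genes (0.23, 0.000587; 0.09 and -0.03), Paneth markers (0.37, 0.0411; 0.61 and 0.43) and enteroendocrine markers (0.18, 0.0411; 0.27 and 0.12) rose. For these 4 lists the adjusted p = 0.732 with an estimated correlation. Gstp1, a glutathione transferase gene, stood at 719 ± 141 against 466 ± 24.1 FPKM, and Gcg, the proglucagon gene, at 117 ± 21.2 against 68.9 ± 12.7. Interferon response genes fell (1 of 29 positive, -0.53, adjusted p = 4.2e-05; -0.54 and 0.62, and adjusted p = 0.732 with an estimated correlation): Irf7, an interferon regulator gene, stood at 30.9 ± 8.63 against 50.8 ± 12.7 FPKM. T and NK cell markers (-0.31, 0.00363; 0.21 and -0.08) and MHC class II genes (-0.39, 0.029; 0.38 and -0.31) fell, both with adjusted p = 0.732 with an estimated correlation. Cholesterol synthesis genes fell (-0.19, 0.0411; 0.00 and 0.31, and adjusted p = 0.865 with an estimated correlation), with Srebf2, the master regulator of this pathway, at 34.7 ± 4.12 against 49.6 ± 4.64 FPKM.

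Camera called 11 of 43 lists in the colon, 0 with an estimated correlation, and fry called the panel and calcium lists (adjusted p = 0.0451 and 0.015), the calcium list in its test for either direction as well (0.000212). Of all tested lists, 17 of 42 lists had the opposite sign within the serial and 14 of 42 within the 4-digit libraries, as did 6 and 4 of 44 named genes. The count was 21 without deficient minusD5718 and 3 with the naming scheme in the fit: the panel (mean 3.25), calcium transport (0.99) and adipocyte (0.67) lists. The interferon mean was then 0.04. The T and NK cell list missed without treated 3xD5720 (0.409), and the MHC class II list without treated 3xD5711 (0.0881), 3xD5720 (0.433) or 3xD5734 (0.082) or deficient 1 (0.0907) or 2 (0.0534). The cholesterol list missed without treated 3xD5711 (0.115), 3xD5720 (0.355) or 3xD5734 (0.14) or deficient 1 (0.101), 2 (0.436) or 3 (0.395). The Paneth list missed without treated 1 (0.196), deficient minusD5718 (0.0846), deficient 3 (0.113) or treated 3xD5711 (0.564), where its mean relative to all genes was -0.02. The enteroendocrine list missed without treated 1 (0.122), 3xD5711 (0.24) or 3xD5734 (0.13) or deficient 3 (0.0728). Relative to all genes, the mean ran from -0.944 to -0.242 for interferon (-0.517 with all libraries), 0.251 to 0.673 for PPAR-alpha (0.471), -0.523 to -0.122 for T and NK cells (-0.292), -0.699 to -0.130 for MHC class II (-0.378), -0.387 to -0.068 for cholesterol (-0.178), -0.023 to 0.836 for Paneth (0.386) and 0.139 to 0.329 for enteroendocrine lists (0.2).

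**Figure D3:**
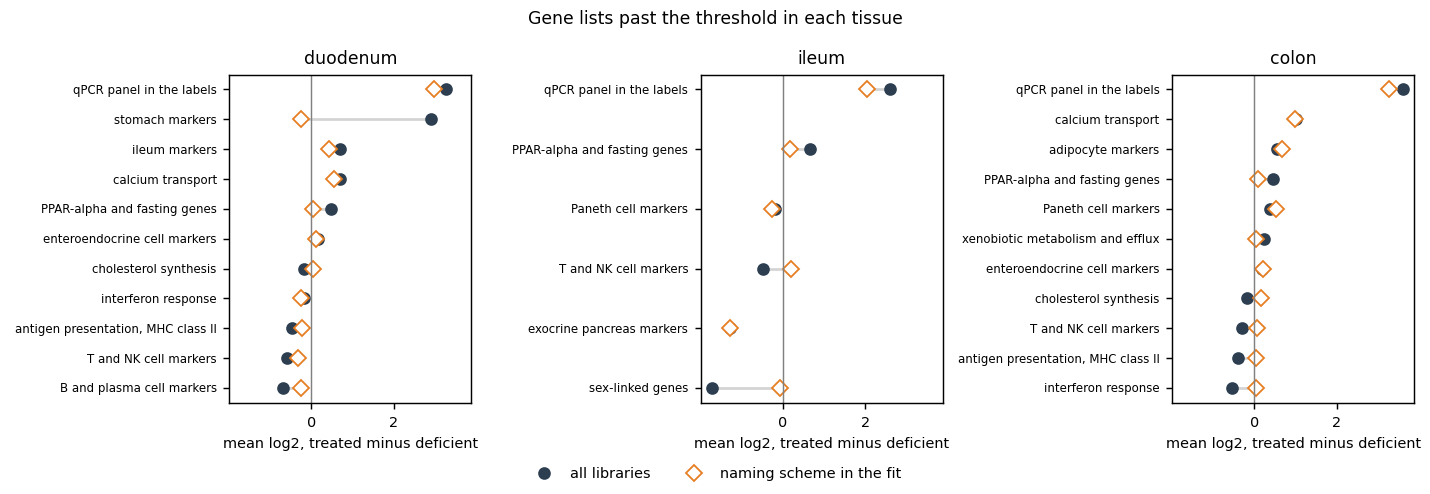
Mean log2 difference, treated minus deficient, of each gene list that passed in the duodenum, ileum and colon (filled circles), with the value when the naming scheme is in the fit (open diamonds). Calcium transport in the colon moves from 1.01 to 0.99, while the stomach markers of the duodenum move from 2.89 to -0.25. The calcium list shares Trpv6 and S100g with the panel. In the ileum the open diamonds rest on treated 1 alone against the deficient libraries.

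The study's title sets the proximal against the distal intestine. The response of Trpv6 was larger in the colon than in the ileum, by 4.21 in log2 (ileum minus colon -4.21 ± 0.93, limma adjusted p = 0.00126 when adjusted over the list alone, here the 5 panel genes tested and Vdr). It was larger in the duodenum than in the ileum by 2.76 ± 0.93 (0.0469), while duodenum minus colon was -1.45 ± 0.90 (0.181). Slc37a2 responded more in the duodenum than in the colon (2.47 ± 0.83, 0.0442). The ileal response of Trpv6 is measured at the floor, with 1 to 24 recovered reads per library, where the pseudocount of 1 flattens it. With pseudocount 0.1 none of these passed, at 0.0696 for Trpv6 of ileum and colon, 0.184 for Trpv6 of duodenum and ileum and 0.0603 for Slc37a2. For Cyp24a1, S100g and Slc30a10 no difference between tissues passed without the replicate block: Cyp24a1 gave 3.01 ± 1.82 for duodenum minus ileum (0.229) and 1.63 ± 1.75 for duodenum minus colon (0.364), and S100g gave -2.52 ± 1.55 for duodenum minus colon (0.181). With single libraries left out, duodenum minus colon ran from 0.14 to 2.36 for Cyp24a1 and from -2.13 to -0.91 for Trpv6. These counts are not independent evidence either, for the same reason.

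Over all genes, limma called 0 differences in response for each pair of tissues. An unadjusted p under 0.05 was reached by 571 of 12450 genes for duodenum and ileum (622 by chance), 254 of 13115 for duodenum and colon (656) and 449 of 13065 for ileum and colon (653). The chance counts assume independent libraries, while libraries of one number resemble each other between tissues, which this fit leaves out. Voom was not run for these contrasts. The smallest p belonged to Ap1g1 for duodenum minus ileum (-2.48 ± 0.45, adjusted p = 0.247), to Fermt3 for duodenum minus colon (1.78 ± 0.35, 0.665) and to Rac3 for ileum minus colon (-1.22 ± 0.20, 0.0972). Cbr2, a carbonyl reductase gene, was at 73.9 ± 37.6 FPKM in treated and 17.2 ± 3.60 in deficient colon, and at 0.614 ± 0.485 against 0.543 ± 0.286 in the duodenum (duodenum minus colon -1.89 ± 0.40, adjusted p = 0.665). With the library number as a replicate block, Rac3 passed for ileum and colon (-1.24, adjusted p = 0.0237) and the panel counts were 2, 2 and 1 instead of 1 each, with Slc37a2 added for duodenum minus ileum (1.89 ± 0.67, 0.0301 adjusted over the list alone) and Slc30a10 for duodenum minus colon (-1.82 ± 0.64, 0.0307). With the naming scheme in the fit the panel counts were 0, 0 and 1. One gene passed for duodenum and ileum without duodenal treated 3xD5711 or deficient 3, and one for duodenum and colon without colonic treated 1 or deficient 3. For ileum and colon it was 1 without ileal treated 3xD5711 or colonic treated 3xD5734, and 2 without colonic deficient 3. The panel count for duodenum and ileum was 0 without any one of duodenal treated 3xD5711 and 3xD5734, duodenal deficient 1, 2 and 3, ileal treated 1, 3xD5711 and 3xD5734 and ileal deficient 1, 2 and 3, and it was 2 without ileal treated 3xD5720. For duodenum and colon it was 0 without any one of duodenal treated 1, 3xD5711 and 3xD5734, duodenal deficient 3, colonic treated 3xD5711 and 3xD5720 and colonic deficient minusD5718, 1 and 2. Leaving out single libraries did not move the count of 1 for ileum and colon.

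Of 11365 genes tested in both the duodenum and colon, 89 were higher at an unadjusted p under 0.05 in both tissues, where independent lists give 14.0, and 83 were lower in both (16.9). Libraries of the same number resemble each other between these tissues, so independent lists set too low a bar: splits other than treatment, applied to both tissues at once, gave a median of 32 and up to 392 such genes, against the 172 of both signs. For duodenum and ileum 49 genes were higher and 21 lower in both, and 9 other splits gave as many as these 70 (median 26, highest 381). For ileum and colon they were 35 and 26, and 8 other splits gave as many as these 61 (24 and 538). At the adjusted threshold 0 calls of limma were shared by any pair, as had to be with 0 calls in the ileum and in the colon. Across genes, which are not independent replicates, r was 0.56 for duodenum and colon (Spearman 0.54, 70% of genes with the same sign; other splits -0.25 to 0.66, median 0.32), 0.28 for duodenum and ileum (0.19, 55.6%; median 0.38) and 0.31 for ileum and colon (0.25, 59%; median 0.29). With the naming scheme in both fits r was 0.57 for duodenum and colon. Groups were fully apart in the same direction in both of these tissues for 70 genes, where independent tissues give 11.6 and the other splits a median of 7 and up to 222. Among them, chosen after their values were seen, are Krt7 (1.07 ± 0.15 in the duodenum, 0.94 ± 0.16 in the colon), Lrrc26, a potassium channel subunit gene (1.13 ± 0.23 and 1.04 ± 0.18), Ifrd1 (0.91 ± 0.15 and 0.63 ± 0.15) and Gstp1 (0.59 ± 0.20 and 0.61 ± 0.15).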

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

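The tests of stomach transcripts, of the lymphocyte and interferon lists by naming scheme or Xist, of genes that switch inside a group of another tissue, and the counts of splits for genes shared at an unadjusted p were chosen after the results were seen. The other counts of splits and the tests of the correlation of duodenum and colon, the one by naming scheme among them, were chosen before.

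Within groups of 4, 21 of 228 groups had 1 library far from the other 3 by Dixon's test, where chance alone gives about 1 in 20. That rate assumes normally spread values. Where the other 3 libraries are all at 0, as for BC023829, Oaz1 and Fermt3, any reads make 1 library outlying. In the duodenum, S100g stood at 3150 FPKM in treated 3xD5720, where the nearest other treated library had 10400. BC023829 stood at 0.0816 FPKM in treated 3xD5711, against 0 in the other 3. Acot2 was at 20.6 FPKM in treated 3xD5720, against 4.96 at the nearest. Cyp24a1 was at 0.418 FPKM in deficient minusD5718, against 0.0185. Slc30a10 was at 14.1 FPKM in deficient 3, against 51.7, and Slc37a2 at 5.1 FPKM in the same library, against 30.6. In the ileum, Vdr was at 53.4 FPKM in treated 3xD5720, against 80.8, Oaz1 at 0.985 FPKM in treated 3xD5711, against 0, and Cpt1a at 38.6 FPKM in treated 1, against 50.4. In the colon, Fermt3 was at 0.244 FPKM in treated 1, against 0, and Cyp24a1 at 0.0814 FPKM in deficient 3, against 0.0183. Fdft1 was at 0.227 FPKM in deficient minusD5718, against 1.09, Hmgcs1 at 18.8 FPKM in the same library, against 56.6, and Il2rb at 1.77 FPKM in deficient 1, against 1.54.

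Stomach transcripts gave further such libraries. In duodenal treated 1, Tff2 was at 126 FPKM (nearest 3520), Pgc at 1.26 (28.4), Gkn1 at 0 (321) and the stomach list at a mean log2 of 1.72 (7.37). In duodenal deficient minusD5718, Pgc was at 39.9 FPKM (1.11), Gkn1 at 557 (0.0282) and the list at 8.23 (1.89).

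Responses of panel genes differed between tissues in the interaction test adjusted over the list alone: Trpv6 by 2.76 for duodenum minus ileum (limma adjusted p = 0.0469) and by -4.21 for ileum minus colon (0.00126), and Slc37a2 by 2.47 for duodenum minus colon (0.0442). With pseudocount 0.1 these were 3.31 (0.184), -4.35 (0.0696) and 2.56 (0.0603), so none passed.

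Library contents followed the naming scheme in the duodenum. All 7 tested stomach markers (100%) were higher in every 4-digit library than in every serial one, and 0% parted treated from deficient libraries, which argues against calcitriol as their source; stomach tissue taken along with one set of duodenal samples may account for them. Sex nearly coincides with the scheme: 71.4% were higher in every library with more Xist than Ddx3y than in every other one. Yet treated 3xD5734, with less, had Gkn1 at 321.5, Gkn2 at 548.5 and Tff1 at 1159 FPKM. The serial libraries, also with less, had at most 0.0282, 0 and 1.342 FPKM. Only treated 3xD5734 tells sex from scheme, so sex is not excluded. For the T and NK cell list of the duodenum the mean log2 went from -0.58 ± 0.28 to -0.33 ± 0.27 (SE) with the scheme in the fit, so treatment and scheme cannot be told apart there: only 1 treated library is serial and 1 deficient library is not. In the colon it went from -0.31 ± 0.29 to 0.06 ± 0.16, though both values lie near their errors. The scheme may thus account for the lower T and NK cell list there. The colonic interferon mean was -0.53, with -0.54 within the serial and 0.62 within the 4-digit libraries, and 0.04 with the scheme. Each scheme holds 1 library of one group, so these values do not decide on the scheme for the interferon list. With Xist as a covariate the means relative to all genes were -0.155 for colonic T and NK cells (adjusted p = 0.11) and -0.265 for colonic interferon genes (0.0191), and in the duodenum -0.485 (1.2e-05) and -0.213 (0.00247). Without it the colonic means were -0.292 and -0.517, so both shrank by a like share, and sex stays open for both colonic lists although the interferon list still passed. Calcitriol stays open for both tissues.

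The duodenal and colonic responses rose and fell together across genes, with r = 0.56. The naming scheme is argued against as the whole source, since r was 0.57 with the scheme in both fits and 0.36 when both tissues were split by it. Animals that gave both tissues may contribute: 5 of the 35 splits, applied to both tissues at once, gave as high an r, the highest other being 0.663 and their median 0.32, so chance together with shared animals was not excluded. The covariance was 0.047 against a median of 0.02 over the other splits. For the 70 genes with groups fully apart in both tissues, 3 of 35 splits gave as many, and the highest, 222, was the split by naming scheme; for the 172 genes at an unadjusted p under 0.05 in both, 5 of 35 splits gave as many, and the highest, 392, was again that split, which is also close to a split by sex. For the other pairs, 10 of 35 splits gave as many for duodenum and ileum (highest other 381) and 9 of 35 for ileum and colon (538), so chance was not excluded. A shared response to calcitriol remains open beside these.

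Genes listed near 0 in one group (at most 0.1 FPKM) and expressed in every library of the other (at least 0.5) numbered 4 in the duodenum, 2 in the ileum and 1 in the colon. Of these 7 cases, 6 (85.7%) also switched between near 0 and expressed inside one group of another tissue, against 93 of 349 other cases of like level (26.6%). By tissue this is 4 of 4 against 41 of 97 in the duodenum and 2 of 2 against 52 of 252 in the ileum. Ap1g1 is among them in both the duodenum and the ileum, and by distinct genes the shares are 5 of 6 (83.3%) and 87 of 337 (25.8%). Reads assigned to another gene model in some libraries may account for genes such as Ap1g1, whose order was opposite in the duodenum and ileum; the exception is Cyp24a1 in the colon. In the duodenum 2 of 35 splits gave as many as 4 such genes, and the highest, 10, was the split by naming scheme, so chance was not excluded. A response to calcitriol of Ap1g1 and BC023829 was not tested apart from this.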

How the results depend on the processing

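The naming scheme and Xist covariates, serial or 4-digit libraries alone, voom and all settings of the panel counts were chosen after seeing the data. So were the overlaps at an unadjusted p and the list counts by fry in place of camera, though fry was planned beside camera. The exclusion of the duodenal library highest in ileum markers and the colonic one highest in pancreas markers was chosen then too. Of 275 alternatives run on 15 summary values, 213 stayed within 1.5 times and 62 moved. Of 3452 run on 166 single genes and lists, 3204 gave the same call and direction, 145 were weaker, 26 stronger, 37 reversed and 40 moved. For every single gene except duodenal Cyp24a1, Ap1g1 and BC023829, the same call means that the gene passed in neither fit. That count thus says little about the size of a difference. 5033404E19Rik for duodenum minus colon (-2.03 in the main fit) ran from -2.33 to -0.35 and counted as the same in 26 of 26. Causes were not tested except where fewer libraries or genes explain a change. Leaving out libraries, 4 against 4 keeps less power, and depth limits low FPKM.

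The 3 duodenal genes became 1 with pseudocount 0.1, the mean filter, the 5 FPKM filter, quantile normalization or the naming scheme, 0 with serial libraries alone, 0 with 4-digit libraries alone, and 1 to 4 leaving out single libraries. The 0 ileal genes became 1 with no filter and 1 with voom, and stayed 0 to 0 leaving out single libraries. The 0 colonic genes became 8 with array weights, 5 in one fit of 23 libraries, 2 with the naming scheme, 675 with serial libraries alone (1 treated library, assumed to vary like the others) and 0 to 3 leaving out single libraries. The panel counts became 2 (naming scheme), 0 (serial) and 1 (4-digit) in the duodenum, 0 (naming scheme) and 0 (serial) in the ileum and 2 (serial) in the colon. Leaving out single libraries gave 4 to 5, 2 to 3 and 4 to 5.

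The list counts of 11, 6 and 11 became 0, 0 and 0 with an estimated correlation, 0, 0 and 2 with fry, 6, 14 and 3 with the naming scheme and 6, 14 and 7 with Xist as a covariate. The colonic count was 20 in the authors' table without deficient minusD5718. Leaving out single libraries gave 4 to 15 in the duodenum, 2 to 13 in the ileum and 8 to 21 in the colon.

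The 0 interaction genes of duodenum and ileum became 1 with pseudocount 0.1 and with the libraries of those 2 tissues alone. They also became 1 without the duodenal library highest in ileum markers (treated 3xD5711) and the colonic one highest in pancreas markers (treated 3xD5720). Other libraries with stomach or pancreas transcripts stayed in that fit. The 0 interaction genes of duodenum and colon became 1 with pseudocount 0.1 and with array weights. Those of ileum and colon became 1 with no filter, 1 with the replicate block (Rac3) and 1 with the naming scheme. Leaving out single libraries gave 0 to 1, 0 to 1 and 0 to 2. The shared calls of 0 became 70 for duodenum and ileum, 172 for duodenum and colon and 61 for ileum and colon at an unadjusted p under 0.05.

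With the naming scheme as a covariate, duodenal Pgc turned to -0.03, Gkn1 to -0.21 and, relative to all genes, stomach markers to -0.24, while the PPAR-alpha list fell from 0.461 to 0.036 and its test turned. Ileal Lck turned to 0.36, Ddx3y to 0.11, Kdm5d to 0.03, Vdr to 0.04 and T and NK cell markers to 0.181. These ileal values compare treated 1 alone with the deficient libraries, as only the serial scheme holds both groups. In the colon Vdr turned to -0.13, cholesterol synthesis to 0.186, interferon response to 0.071, MHC class II to 0.066 and T and NK cell markers to 0.091. Between tissues, Vdr for ileum minus colon turned to 0.17. With Xist as a covariate, ileal Vdr turned to 0.05, Ddx3y to 0.05, Kdm5d to 0.16, Eif2s3y to 0.02 and the sex-linked list to 0.09. Ileal Slc37a2, at 0.00, was -0.03 with pseudocount 0.1, -0.01 with 0.5 and 0.00 after median-ratio rescaling, and -0.07 to 0.11 leaving out single libraries. Colonic Vdr was -0.03 after quantile normalization. Leaving out single libraries, Vdr ran from -0.28 to 0.07 in the ileum, from -0.12 to 0.15 in the colon and from -0.34 to 0.02 for ileum minus colon. S100g for duodenum minus ileum ran from -2.42 to 0.71, and Slc30a10 for ileum minus colon from -1.17 to 0.16.

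No paired analysis was possible because treated and deficient columns of a tissue share 1 number alone, and the columns do not tie to the labels' replicates. Between tissues, the replicate block changed no other call of genes than Rac3 and the panel counts of 2, 2 and 1. Labels' sex and age as covariates were not run for want of a tie between columns and labels. Summed FPKM of repeated symbols was not run since no symbol repeats. EdgeR and DESeq2 were planned for deposited counts only and were not run; voom alone was run on the recovered reads.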

Other observations

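The counts of splits for the duodenal and colonic gene calls and for genes at an unadjusted p were chosen after those results were seen, and the other tests here before.

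The makeup of the samples differed from library to library. Exocrine pancreas markers had a mean log2(FPKM + 1) of 4.77 in duodenal treated 3xD5734 and of 7.50 to 10.2 in the other duodenal libraries. In the colon they reached 9.25 in treated 3xD5720, 6.92 in deficient 1 and 6.81 in deficient 3, and lay at 1.44 to 2.49 in the other 5. Ileum markers stood at 5.23 in duodenal treated 3xD5711 and at 3.20 to 4.59 in the other duodenal libraries. Reg3b, an antimicrobial lectin gene, was the most abundant transcript in 6 of the 23 libraries, among them ileal treated 3xD5720 and ileal deficient 3, where the top 10 genes took 30.3% and 27.5% of the summed FPKM.

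Whether other splits of the libraries give as large a result was counted for each comparison. For the panel genes adjusted over the list alone, the real split was the 1 split of 35 with as many in each tissue: 5 in the duodenum (highest other 3), 2 in the ileum (1) and 4 in the colon (2). The panel may have been chosen on these samples, so these counts do not decide whether chance can be excluded. For the 3 duodenal genes, 3 of 35 splits gave as many, with a highest other of 56 and 50 in the split by naming scheme, so chance cannot be excluded. A split that calls many times the real count points to a structure of the samples other than treatment, and the split by naming scheme is close to a split by sex. For genes at an unadjusted p under 0.05, 6 of 35 splits gave as many as 1103 in the duodenum (highest other 2855), 9 of 35 as many as 709 in the ileum (2070) and 7 of 35 as many as 746 in the colon (2112, the split by naming scheme), so chance cannot be excluded for these counts either. The 0 genes of the ileum and colon are matched by all 35 of 35 splits, as any count of 0 must be, and say nothing; the highest other was 2 in the ileum and 10, the split by naming scheme, in the colon. The same holds for the interaction counts of 0, matched in 100 of 100 shuffles of treatment within tissues, with highest others of 670 for duodenum and ileum, 38 for duodenum and colon and 43 for ileum and colon. For the lists, 27 of 35 splits gave as many as 11 in the duodenum (highest other 21), 33 of 35 as many as 6 in the ileum (20) and 21 of 35 as many as 11 in the colon (22), so chance cannot be excluded for the counts of lists.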
